A study of Mus musculus with 6 samples.

How the data were processed

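The series holds 6 arrays of sorted mouse thymocytes, 2 for each of 3 stages: DP, CD4intCD8+ and CD8SP. Per the labels, the 3 populations were sorted with antibodies to CD4 and CD8 from 6 age- and sex-matched N15 transgenic, Rag2-deficient mice aged 5 to 6 weeks, for a pair of independent experiments, and total RNA was converted to biotin-labelled cRNA. Stage and replicate number were taken from the sample titles. Beyond the 2 experiments nothing in the labels ties an array to separate animals, so that p-values measure the spread between these arrays.

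The deposited table gives 1 linear intensity per probe and array, with 45101 rows, 64 of them control probes, and 0 missing values. How the authors computed the deposited intensities, and the software, scaling and normalization between arrays, is not given in the sources used here. The values themselves show that a background or mismatch signal had been subtracted, because 9720 values of non-control probes (3.60%) lay below 0, and that the arrays had been brought to a common scale, because the array medians lay between 24.9 and 25.7. Scanner files were not used here. Subtraction and scaling by the authors limit what low values can show: a gene near 0 has no usable fold change, and a change in the total RNA per cell cannot be seen.

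Of the 45037 non-control probes, 34945 had a single gene symbol in the platform annotation, 932 had several and 9160 had none; 34741 were matched through their Entrez number to a table of gene names (assembly GRCm38.p6, used for names alone), and 0 symbols needed updating. Probes with several symbols or none were left out of the gene tests. Each of the 18193 genes was represented by its probe with the highest mean, so that probes of a gene that disagree are not averaged. Values below 0 were set to 0 and log2(intensity + 5.84) was taken, where the pseudocount of 5.84 is the 10th percentile of the positive values; fold changes are on this scale, understate the change of dim genes, and for genes near the pseudocount depend on it in size and rank. Genes with a mean under the 40th percentile (log2 5.19, an intensity of 30.8) were left out, which removed 7277 genes and kept 10916. No value is adjusted for a second time between arrays.

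All 6 arrays were fitted together with limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3, statmod 1.5.0), with stage as the only term, 3 residual and 6.05 prior degrees of freedom. The contrasts were CD4intCD8+ against DP, CD8SP against CD4intCD8+, CD8SP against DP, and CD4intCD8+ against the mean of the other stages, with a moderated F test over the stages. Benjamini-Hochberg adjustment was applied within each contrast and an adjusted p under 0.05 was called. Values after ± are standard errors of log2 changes from this fit (median 0.17 for the pairwise contrasts) or, where marked SD, standard deviations over the 2 arrays. Groups of 2 are too small for tests of outlying samples or of other splits of the samples.

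The design, 28 gene lists with 516 memberships (474 on the array), the rule for named genes and the alternatives were fixed before the data were examined. The lists cover the double-positive stage, receptor response, maturation and egress, the CD8 and CD4 lineages, chemokine receptors, guidance molecules, integrins, proliferation, receptor signalling, MHC class I, interferon, Gimap genes, cell death, cytokine receptors, NF-kappaB, glycolysis, cholesterol, transcription factors, stress, and markers of double-negative, B, myeloid, dendritic, epithelial, erythroid, natural killer and gamma delta T cells. The 22 lists with at least 5 tested members were compared with other genes by limma's camera with a preset correlation of 0.01, in 66 tests adjusted together. Of these 26 were called, 17 up and 9 down; with the correlation estimated from the data 0 were called, and by fry, which asks whether a list moves one way on balance, 1. The 6 other lists are described by counts. Named genes are the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap, up to 4 members of each list with the largest change, and 20 anchor genes of thymocyte development; names outside this rule are marked as chosen after their values were seen. Of the anchors, 2 are not used here. Cd4, Plxnd1, Ccr4 and Zbtb7b lay under the filter and are given from the fit without it.

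Replicate numbers are shared between the stages. After subtraction of the stage means, arrays of the same number deviated together in each pair of stages, with correlations across genes of 0.26 (DP and CD4intCD8+), 0.21 (DP and CD8SP) and 0.30 (CD4intCD8+ and CD8SP), while random numbering gives 3 positive values in 25% of cases. Since the 3 correlations lie above 0.1 and the labels name a pair of independent experiments, the numbers were taken to pair the samples, and the fit with the replicate number as a block is given in the report where it moves a printed count of genes or list members by more than 1.5 times, calls a list, or calls a gene that the text states as not called. All other counts, errors and adjusted p come from the fit fixed beforehand, which ignores this pairing.

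The gene test was tested on simulated data with 200 of 10916 genes changed, in 20 runs. With spreads as estimated per gene, log2 changes of 1 were recovered for 89.2%, 88.0% and 89.2% of genes in the contrasts CD4intCD8+ against DP, CD8SP against CD4intCD8+ and CD8SP against DP, log2 changes of 2 for 99.9%, 99.8% and 99.9%, and 8.52%, 7.51% and 6.99% of calls were false. With spreads drawn from the fitted prior, as the model assumes, the shares were 69.0%, 69.4% and 66.9%, then 98.3%, 98.6% and 98.3%, with 4.94%, 5.05% and 4.50% false. In 40 simulated runs camera called 40 lists of 20 genes shifted by 0.5 and 1 unshifted list, at an unadjusted p under 0.05. Genes were drawn independently in all these simulations. In the data the estimated correlation within a list ran from -0.19 (myeloid markers) to 0.85 (proliferation). The runs therefore do not check how often camera calls unshifted lists of correlated genes.

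The alternatives were quantile normalization, median centring, no filter, a 60th-percentile filter, the mean of all probes of a gene, each probe on its own, the replicate block, only the 4 arrays compared, no intensity trend, array weights, a 2-fold threshold, pseudocounts at the 1st and 25th percentiles (0.92 and 11.8), camera with an estimated correlation, fry, and leaving out each array. A covariate for the actin 3' to 5' ratio, and the list counts without CD4intCD8+ replicate 2, were added after the data were seen. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.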

Results

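Gene expression was measured on 6 microarrays in thymocytes of mice that carry the N15 T cell receptor transgene and lack Rag2, so that receptor genes other than the transgene are not assembled. Cells were sorted on surface CD4 and CD8 at 3 stages, with 2 arrays per stage: double-positive (DP) cells, which carry both coreceptors, CD4intCD8+ cells, in which surface CD4 is intermediate, and CD8 single-positive (CD8SP) cells. The comparisons ask how expression changes from DP through the intermediate stage to CD8SP. Median probe intensity lay between 24.9 and 25.7 on every array, and between 2.78% and 4.33% of the values of an array were below 0. Across genes, the Pearson correlation of the 2 arrays of a stage was 0.983 for DP, 0.975 for CD4intCD8+ and 0.978 for CD8SP; genes are not independent replicates. The first principal component carried 60.3% of the variance and placed the DP arrays at -31.7 and -32.4, the CD4intCD8+ arrays at 6.11 and 12.2 and the CD8SP arrays at 20.5 and 25.2. The actin 3' to 5' signal ratio, which rises when RNA is shorter, was 1.98 and 2.14 in DP, 2.37 and 3.47 in CD4intCD8+ and 2.28 and 2.62 in CD8SP. CD4intCD8+ replicate 2 thus had the highest ratio of the 6 arrays. The number of arrays limits the precision of every value.

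The coreceptor transcripts, whose products were the sorting markers, were lower after the DP stage. Cd4 intensity was 351 and 515 on the DP arrays, -33.0 and 11.8 on the CD4intCD8+ arrays and -65.8 and -68.6 on the CD8SP arrays, so that no fold change is given. In the fit without a filter on dim genes Cd4 fell from DP to CD4intCD8+ (adjusted p = 0.000569), a call lost without the intensity trend (adjusted p = 0.0994). Cd8a fell from a mean intensity of 3359.7 ± 292 (SD, n = 2) in DP to 1921 ± 623 in CD4intCD8+ (log2 change -0.84 ± 0.18, SE; limma adjusted p = 0.0215), and Cd8b1 fell by 0.84 ± 0.13 on the log2 scale (adjusted p = 0.00765). Neither changed by the test from CD4intCD8+ to CD8SP (log2 change -0.14 ± 0.18 for Cd8a and 0.14 ± 0.13 for Cd8b1). The Cd8a call was lost without DP replicate 1 or DP replicate 2 (adjusted p = 0.0859 and 0.126), and the Cd8b1 call without DP replicate 2 (adjusted p = 0.0625). With the actin ratio as a covariate Cd8a changed by -0.33 and Cd8b1 by -0.49, and both calls were lost (adjusted p = 0.308 and 0.0522). The Cd8a call was also lost without the intensity trend (adjusted p = 0.0643). Rag2, the gene inactivated in these mice, gave a signal of 165 ± 39.9 in DP; whether its probe lies in the deleted part is not given in the sources used here, so this signal checks no label. Zbtb7b, a transcription factor of the CD4 lineage, had mean intensities of 26.1 ± 4.73 in DP, 30.9 ± 1.08 in CD4intCD8+ and 33.0 ± 7.14 in CD8SP, and Ccr4 24.4 ± 4.87, 16.2 ± 4.99 and 10.7 ± 0.98. Both lay under the filter on dim genes and were not called without it. Plxnd1, a receptor for semaphorins that was also under the filter, fell from 195 ± 33.7 in DP to 15.6 ± 0.51 in CD4intCD8+ (log2 change -3.22 ± 0.32, adjusted p = 0.00134 without the filter), a call lost without the intensity trend (adjusted p = 0.0994).

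From DP to CD4intCD8+ cells, Rag1, which encodes a subunit of the recombinase that assembles receptor genes, fell by 3.11 ± 0.23 on the log2 scale (SE, adjusted p = 0.000659), from a mean intensity of 1050.1 to 117. Ccnd2, which encodes cyclin D2, rose by 2.92 ± 0.23 (adjusted p = 0.000672), from 105 to 847. Itgae, the alpha chain of the CD103 integrin, rose by 2.53 ± 0.20, from 51.5 to 323, and the surface protein gene Cd7 by 2.75 ± 0.18. Nr4a3, an orphan nuclear receptor induced by T cell receptor signals, rose by 2.39 ± 0.14 (adjusted p = 0.000333), and Il2rb, a chain shared by the receptors for interleukins 2 and 15, by 2.27 ± 0.23. The rule for the largest rises also named Trpm1 (mean intensity 5.86 in DP and 78.8 in CD4intCD8+), Adam19 (10.7 and 70.1) and Tbc1d8 (9.97 and 51.0). Their DP levels lay near the pseudocount of 5.84, which sets the size and rank of their changes, so no fold change is given for them. By the same rule, among genes that passed the filter on dim genes, the largest falls after Rag1 were those of Rag2 (-2.63 ± 0.47), Tctex1d1 (-2.31 ± 0.24), Wnt8b (-2.16 ± 0.28), Fbxl12 (-2.09 ± 0.13), Nav2 (-1.95 ± 0.31), Aqp11 (-1.85 ± 0.36) and Spo11 (-1.85 ± 0.18). Cd4 and Plxnd1, which lay under the filter, are not ranked here.

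In total 1277 of the 10916 genes tested changed from DP to CD4intCD8+ at an adjusted p under 0.05, of which 749 were higher and 528 lower in CD4intCD8+; 215 and 86 of them changed at least 2-fold. The count was 317 without DP replicate 1, 187 without DP replicate 2 and 473 without CD4intCD8+ replicate 2. It was 2562 with the replicate number as a block, 764 with the mean of all probes of a gene, 801 without the intensity trend and 406 with the actin ratio as a covariate. Of the 16 leading genes, 5 lost their call when an array was left out: Rag2 and Aqp11 without DP replicate 1 or DP replicate 2 (adjusted p from 0.0617 to 0.101), Wnt8b and Nav2 without DP replicate 2 (0.0552 and 0.0719), and Tbc1d8 without any array but DP replicate 2 (from 0.0518 to 0.0971). Tbc1d8 was also not called without the filter, without the trend, with only the 4 arrays compared or with the actin covariate (from 0.0536 to 0.267). Trpm1 had a log2 change of 0.18 with the smallest pseudocount (adjusted p = 0.631), because another probe then stood for the gene; the probe reported gave 3.70 there. The rise of Trpm1 thus rests on 1 probe that another does not share.

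Genes of the double-positive stage fell as a group: 13 of the 18 tested members were lower in CD4intCD8+, 0 were higher and 5 were not called, against 15 lower when adjusted over the list alone. Limma's camera test placed the list below other genes (adjusted p = 8.31e-11; adjusted p = 0.501 with an estimated correlation). Besides the recombinase genes, Ets2 fell by 1.51 ± 0.11 and Themis, which tunes receptor signalling during selection, by 0.74 ± 0.10. The chemokine receptor gene Ccr9 fell by 0.48 ± 0.09. Of 21 genes of the T cell receptor complex and its proximal signalling, 6 fell and 0 rose (10 fell adjusted over the list alone and 13 with the block), among them Sla, an adaptor that promotes receptor turnover (-0.76 ± 0.10), the costimulatory receptor Cd28 (-0.79 ± 0.17) and the adaptor Lat (-0.59 ± 0.11). The camera adjusted p was 6.46e-06, and adjusted p = 0.662 with an estimated correlation. Among 29 thymocyte transcription factors 10 fell and 2 rose (14 and 5 adjusted over the list alone and with the block). The camera adjusted p was 0.000431 (adjusted p = 0.662 with an estimated correlation). Myb fell by 1.01 ± 0.12 and Gfi1 by 0.91 ± 0.18, while Ikzf3 (0.89) and Ikzf2 (0.57), named after their values were seen, rose. Without CD4intCD8+ replicate 2, the array with an actin ratio of 3.47, the counts that fell were 13, 2 and 7. Calls were lost without DP replicate 1 or DP replicate 2 for Ccr9, Cd28 and Gfi1 (adjusted p from 0.0664 to 0.113), without DP replicate 2 for Lat (0.0803), and without CD4intCD8+ replicate 2 for Cd28 and Lat (0.0882 and 0.0648). Ccr9, Cd28 and Lat also lost theirs without the trend (from 0.0535 to 0.0822) and with the actin covariate (from 0.126 to 0.300), where each changed by -0.41.

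Proliferation genes were higher in CD4intCD8+ cells: 13 of 29 rose, 0 fell and 16 were not called (22 rose adjusted over the list alone and 25 with the block). Camera gave the list an adjusted p of 1.12e-10 (adjusted p = 0.687 with an estimated correlation). The examples were factors that load or form the replicative helicase, Cdc6 (1.86 ± 0.32), Gins2 (1.65 ± 0.30) and Mcm3 (1.36 ± 0.17), and the S-phase cyclin gene Ccne2 (1.29 ± 0.22). Mki67 (0.60, adjusted p = 0.0878) and Top2a (0.44, adjusted p = 0.176), named after their values were seen, were not called, but were with the block (adjusted p = 0.00514 and 0.0399). Of 15 genes of the CD8 and cytotoxic lineage 6 rose and 2, Cd8a and Cd8b1, fell (7 and 2 adjusted over the list alone). By camera, the list had an adjusted p of 0.0226 (adjusted p = 0.735 with an estimated correlation). Nkg7, a granule protein gene, rose by 2.04 ± 0.24 and the cathepsin gene Ctsw by 1.81 ± 0.25, whereas Runx3, the CD8-lineage transcription factor, had a log2 change of 0.38 ± 0.18 (adjusted p = 0.215, and 0.0414 with the actin covariate). Without CD4intCD8+ replicate 2, whose actin ratio was 3.47, 7 proliferation genes rose and 5 genes of the CD8 list rose. The camera call of the CD8 list was lost without CD4intCD8+ replicate 1 (adjusted p = 0.157) and with the 60th-percentile filter (adjusted p = 0.0801). Without DP replicate 1 or DP replicate 2, Cdc6, Gins2 and Ccne2 lost their calls (adjusted p from 0.0556 to 0.0843), and Ctsw did without DP replicate 2 (0.0509). With the actin covariate Gins2 changed by 0.83 and Ccne2 by 0.70, and neither was called (adjusted p = 0.0953 and 0.0995).

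Camera placed 3 further lists above other genes at this step, with few members called and 0 of the 3 called by fry (adjusted p from 0.179 to 0.553). For MHC class I presentation 3 of 18 genes rose, both over all genes and adjusted over the list alone (6 rose and 1 fell with the block): the peptide trimmer Erap1 (0.79 ± 0.16), the immunoproteasome subunit Psmb9 (0.66 ± 0.13) and B2m (0.38), the last named after its value was seen. The list had a camera adjusted p of 0.00459 (adjusted p = 0.687 with an estimated correlation). For interferon-stimulated genes it was 3 of 25, a share close to the 11.7% of all tested genes that were called, also adjusted over the list alone (11 rose and 1 fell with the block): Ifit1 (1.98 ± 0.48), Bst2 (1.49 ± 0.32) and Gbp3 (1.46 ± 0.25). Against other genes, camera gave an adjusted p of 0.00459 (adjusted p = 0.799 with an estimated correlation). For cholesterol synthesis and uptake 4 of 15 rose (7 adjusted over the list alone and with the block): Idi1 (1.34 ± 0.24), Cyp51 (1.23 ± 0.27), Sqle (1.13 ± 0.25) and Hmgcs1 (0.72 ± 0.16). The camera adjusted p was 0.0176 (adjusted p = 0.687 with an estimated correlation). Without CD4intCD8+ replicate 2 (actin ratio 3.47) the counts that rose were 4, 7 and 1. The class I call was lost without CD4intCD8+ replicate 1 (adjusted p = 0.233), the interferon call without DP replicate 2 or CD4intCD8+ replicate 1 (0.296 and 0.444), and the cholesterol call without CD4intCD8+ replicate 2 (0.0646), with the mean of all probes (0.0536) and with the actin covariate (0.211). Each gene named here other than B2m lost its call without DP replicate 2 (adjusted p from 0.0557 to 0.165); Psmb9, Idi1, Cyp51, Sqle and Hmgcs1 also did without DP replicate 1 (from 0.0728 to 0.132), Ifit1 without CD4intCD8+ replicate 1 (0.063), and Psmb9, Cyp51, Sqle and Hmgcs1 without CD4intCD8+ replicate 2 (from 0.0676 to 0.152). With the actin covariate Psmb9 and the 4 cholesterol genes lost their calls (from 0.113 to 0.386). Psmb9 was then at 0.58, close to its change as reported, while Idi1, Cyp51, Sqle and Hmgcs1 were at 0.73, 0.55, 0.53 and 0.37. Calls were also lost for Ifit1 without the trend (0.0659) and for Erap1 with the mean of all probes (0.0613).

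Maturation and egress genes moved both ways at this step, with 6 of 21 higher and 2 lower (11 and 5 adjusted over the list alone, 11 and 6 with the block, and 9 and 1 without CD4intCD8+ replicate 2). Slfn1 rose by 2.05 ± 0.34, Dapl1 by 1.69 ± 0.36 and S1pr1, the sphingosine phosphate receptor that guides thymic exit, by 1.38 ± 0.32, while Ifngr1 fell by 1.30 ± 0.12. Bcl2, which encodes a survival factor, rose by 0.64 ± 0.14. Il7r (1.05 ± 0.30, adjusted p = 0.0512), Ccr7 (1.08 ± 0.33, adjusted p = 0.0682) and Klf2 (1.07 ± 0.32, adjusted p = 0.0599) were not called, but were with the block (adjusted p = 0.0192, 0.000452 and 0.00289). Ccr7 and Klf2 were also called without CD4intCD8+ replicate 2 (0.0245 and 0.0124) and with the actin covariate (0.0034 and 0.00509), Klf2 without DP replicate 1 (0.047), and Il7r under 6 other settings (from 0.0116 to 0.0457). The list was not called by camera (adjusted p = 0.109; adjusted p = 0.799 with an estimated correlation), but was with the block (0.0263), without the filter (0.0385), with the actin covariate (3.34e-06) and without DP replicate 1 (0.0118) or CD4intCD8+ replicate 2 (0.000561). Of 22 response genes of T cell receptor signalling 4 rose and 2 fell (7 and 3 adjusted over the list alone, and 7 and 4 with the block), with Egr3 at 1.16 ± 0.20, Tnfrsf9 at 0.98 ± 0.22 and Tox at -0.76 ± 0.16; Cd69 (0.10 ± 0.24, adjusted p = 0.835) was not called, and Cd5 (-0.34 ± 0.10, adjusted p = 0.0545) was with the block (0.0183) and the 60th-percentile filter (0.0443). Their median was -0.09 and their mean 0.17, and the camera test pointed down (adjusted p = 0.991; adjusted p = 0.997 with an estimated correlation); without CD4intCD8+ replicate 2 the median was 0.16, and with the actin covariate it was 0.34 and the list was called (adjusted p = 0.00192). Calls were lost without DP replicate 2 for Slfn1, Dapl1, S1pr1, Bcl2, Egr3, Tnfrsf9 and Tox (adjusted p from 0.0556 to 0.12), without DP replicate 1 for Dapl1, Bcl2, Egr3, Tnfrsf9 and Tox (from 0.0649 to 0.153), without CD4intCD8+ replicate 1 for Bcl2 and Tnfrsf9 (0.0817 and 0.061) and without CD4intCD8+ replicate 2 for Tox (0.101). With the actin covariate Dapl1 and Tox lost theirs, at 1.32 and -0.39 (0.165 and 0.317), without the trend S1pr1, Bcl2 and Tox did (from 0.0513 to 0.0517), and with the mean of all probes Bcl2 changed by 0.32 (0.246). Guidance genes were called lower by camera only without CD4intCD8+ replicate 2 (0.0197) and with the actin covariate (0.0185), and stress genes only without DP replicate 2 (0.043).

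**Figure D1:**
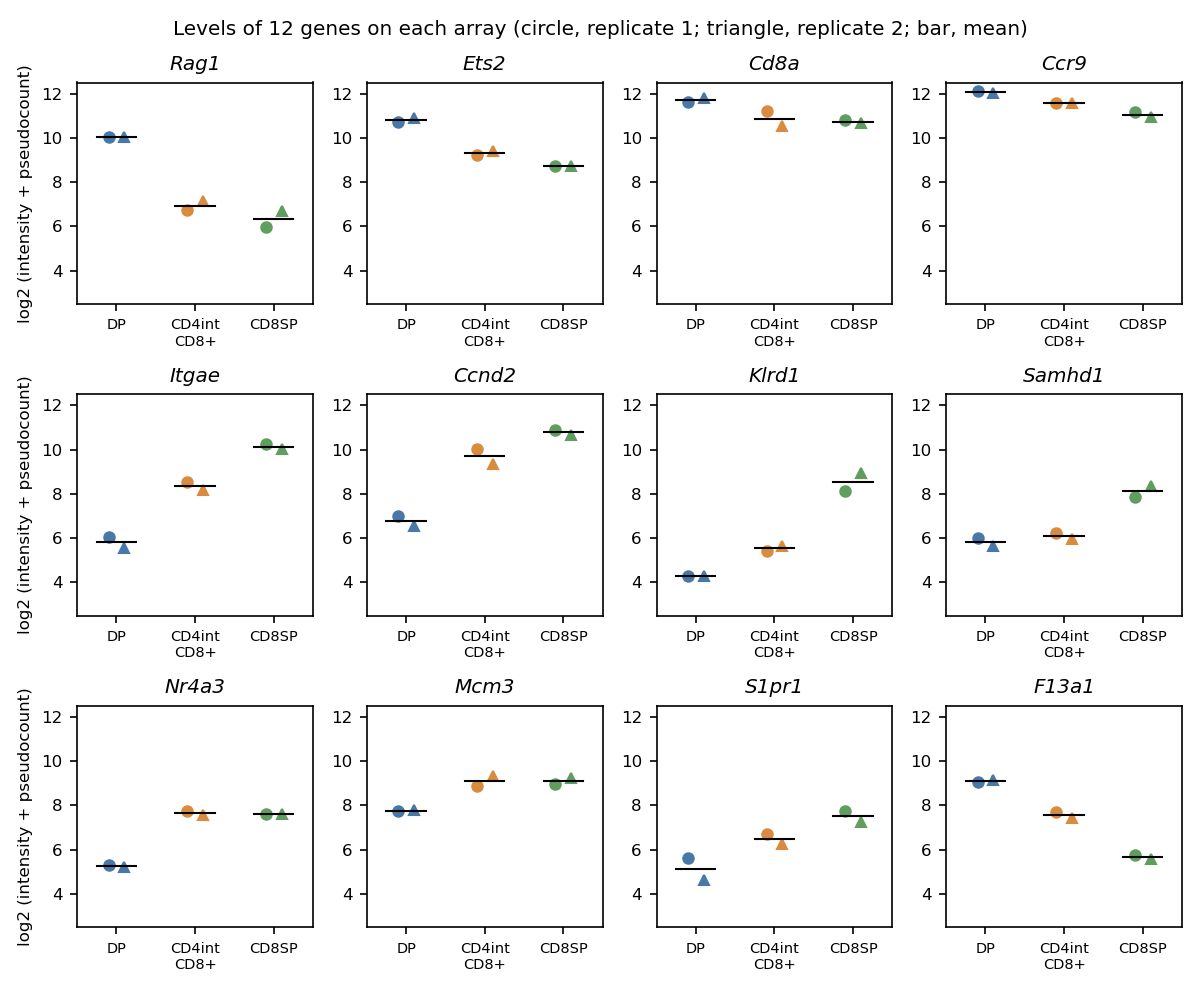
Expression of 12 named genes on each of the 6 arrays, as log2(intensity + pseudocount) against stage (DP, CD4intCD8+, CD8SP); circles are replicate 1, triangles replicate 2 and bars the mean of the 2 arrays. Rag1 falls mainly at the first step, Nr4a3 has log2 means of 5.27, 7.66 and 7.61, and Klrd1 and Samhd1 rise mainly at the second step.

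From CD4intCD8+ to CD8SP cells few genes passed the test in the fit without the replicate block, 13 against 227 with it. Klrd1, which encodes the CD94 receptor chain, rose by 3.0 ± 0.25 on the log2 scale (adjusted p = 0.00407), and Itgae rose again, by 1.78 ± 0.20 (adjusted p = 0.0145), from a mean intensity of 323 to 1120.4. Samhd1, a nucleotide hydrolase gene, rose by 2.03 ± 0.21 and Igfbp4, which encodes a binding protein of insulin-like growth factors, by 1.90 ± 0.20. Lcn4 (2.04 ± 0.23), Btbd11 (1.94 ± 0.22), Slc17a9 (1.74 ± 0.24) and the cytokine gene Clcf1 (1.63 ± 0.21) also rose. F13a1, the A subunit of coagulation factor XIII, fell by 1.89 ± 0.15 (adjusted p = 0.00407), and Ssbp2 by 0.84 ± 0.11.

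In total 13 of 10916 genes changed at this step, 11 higher and 2 lower in CD8SP (11 and 4 after quantile normalization), while 1049 genes had an unadjusted p under 0.05. Without CD8SP replicate 2 the balance turned over: 14 genes were called, 5 higher and 9 lower, and 5 of the 14 were among the 13. The count was 227 with the block, 137 higher and 90 lower. It was 6 without DP replicate 1, 6 without DP replicate 2, 70 without CD4intCD8+ replicate 1 and 7 without CD8SP replicate 1. It was 8 with the 60th-percentile filter, 2 with the mean of all probes, 8 with only the 4 arrays compared and 34 with the actin covariate. Of the 10 named genes, Klrd1, Samhd1 and F13a1 kept their calls without each array. Itgae and Igfbp4 lost theirs without CD8SP replicate 1 (adjusted p = 0.0913 and 0.0677), Lcn4 without either CD8SP array (0.102 and 0.0898), Btbd11 without either DP or either CD8SP array (from 0.0572 to 0.0962), and Slc17a9, Clcf1 and Ssbp2 without any array but CD4intCD8+ replicate 1 (from 0.0763 to 0.173). With the mean of all probes, Samhd1 (0.118), Itgae (0.058) and the other 6 named genes besides Klrd1 and F13a1 were not called (from 0.056 to 0.544). Clcf1 had a log2 change of 0.31 with the smallest pseudocount (0.891), where another probe stood for the gene; the probe reported gave 1.73 there. With only the 4 arrays compared, Slc17a9, Clcf1 and Ssbp2 were not called (from 0.0658 to 0.115). Slc17a9 was also lost without the filter (0.0512) and with the smallest pseudocount (0.0718), and Ssbp2 without the trend (0.145).

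By camera with the preset correlation, several lists shifted at this step although few of their members were called. With an estimated correlation 0 lists were called at this step, and by fry 0. Of 21 maturation and egress genes, 1, Samhd1, rose and 0 fell (12 and 1 adjusted over the list alone, 11 and 0 with the block). Camera gave the list an adjusted p of 7.28e-10 (adjusted p = 0.662 with an estimated correlation). Dapl1 (1.83, adjusted p = 0.111), Il7r (1.76 ± 0.30, adjusted p = 0.0886) and S1pr1 (1.01 ± 0.32, adjusted p = 0.320) were not called, but were with the block (adjusted p = 0.011, 0.0114 and 0.0166). Dapl1 and Il7r were also called without CD8SP replicate 1 (0.00449 and 0.00846) and with the actin covariate (0.0357 and 0.0347), and Il7r without CD4intCD8+ replicate 1 (0.0312). Of 15 genes of the CD8 list, 2, Klrd1 and Itgae, rose (6 adjusted over the list alone and with the block); Ccl5 had a log2 change of 2.36 ± 0.72 (adjusted p = 0.303, 0.0279 with the block and 0.00376 without CD8SP replicate 1). By camera, the list had an adjusted p of 7.74e-07 (adjusted p = 0.662 with an estimated correlation). Genes of the double-positive stage shifted down with 0 of 18 called (4 lower adjusted over the list alone, 3 with the block), with Rag1 at -0.59 ± 0.23 and Ccr9 at -0.54 ± 0.09 (adjusted p = 0.448 and 0.0886, and 0.102 and 0.00677 with the block); Ccr9 was also called with the actin covariate (0.0347). The list had a camera adjusted p of 1.39e-07 (adjusted p = 0.576 with an estimated correlation). Cytokine receptor genes shifted up with 0 of 21 called (6 adjusted over the list alone, 5 with the block). Against other genes, camera gave an adjusted p of 0.000248 (adjusted p = 0.675 with an estimated correlation). These 4 lists kept their camera calls without each array.

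The camera calls of 6 further lists at this step were lost when single arrays were left out. Interferon-stimulated genes shifted up (0 of 25 called, 0 adjusted over the list alone, 5 with the block), but not without CD4intCD8+ replicate 2 (0.536) or CD8SP replicate 1 (0.317), nor with the actin covariate (0.579). The camera adjusted p was 0.000119 (adjusted p = 0.799 with an estimated correlation). MHC class I genes shifted up (0 of 18 called, 2 adjusted over the list alone and with the block), but not without CD4intCD8+ replicate 2 (0.164) or with the actin covariate (0.0745). Camera gave the list an adjusted p of 0.00143 (adjusted p = 0.687 with an estimated correlation). Integrins and adhesion genes shifted up with only Itgae called among 17 (4 up and 1 down adjusted over the list alone and with the block), but not without CD4intCD8+ replicate 2 (0.102), without CD8SP replicate 1 (0.0838) or with the actin covariate (0.0745). By camera, the list had an adjusted p of 0.00457 (adjusted p = 0.662 with an estimated correlation). T cell receptor response genes shifted down (0 of 22 called, 1 adjusted over the list alone and with the block), but not without CD4intCD8+ replicate 1 (0.907) or CD8SP replicate 2 (0.841), nor with the 60th-percentile filter (0.0801). The list had a camera adjusted p of 0.0192 (adjusted p = 0.799 with an estimated correlation). Proliferation genes shifted down with a median of -0.20 (0 of 29 called, 0 adjusted over the list alone). Against other genes, camera gave an adjusted p of 0.0351 (adjusted p = 0.808 with an estimated correlation). Their median was 0.13 without CD4intCD8+ replicate 2, the array with an actin ratio of 3.47, 0.10 without CD8SP replicate 1 and 0.15 with the actin covariate. The call was lost without either array (0.0586 and 0.391) and without the trend (0.0636), and with the actin covariate the list was called in the opposite direction (0.0369). The B cell markers shifted up (0 of 5 called, 1 adjusted over the list alone), but not without CD4intCD8+ replicate 2 (0.173), without CD8SP replicate 1 (0.0683), with the mean of all probes (0.0601) or with the actin covariate (0.0745). The camera adjusted p was 0.0192 (adjusted p = 0.662 with an estimated correlation). Chemokine and sphingosine phosphate receptors were called with the block (0.0200), without the filter (0.0427) and without CD4intCD8+ replicate 1 (0.0297), and otherwise not (adjusted p = 0.0922; adjusted p = 0.662 with an estimated correlation). Of the other lists not called, 4 gained a call when arrays or the covariate changed (adjusted p from 0.209 to 0.296 as reported). T cell receptor complex genes (0.000561, 0.00279 and 0.000189), transcription factors (0.0225, 0.0288 and 0.0105) and CD4 lineage genes (0.0389, 0.0179 and 0.0156) shifted down without CD4intCD8+ replicate 2, without CD8SP replicate 1 and with the actin covariate. Gimap genes shifted up without CD4intCD8+ replicate 1 (0.00229).

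Across both steps, from DP to CD8SP, Itgae rose by 4.31 ± 0.20 on the log2 scale (adjusted p = 2.23e-05), a 19.9-fold change, and Klrd1 by 4.24 ± 0.25 (adjusted p = 3.71e-05). Ccnd2 rose by 4.01 ± 0.23, to a mean intensity of 1759.8, Cd7 by 3.62 ± 0.18 and Dapl1 by 3.52 ± 0.36. The rule also named Trpm1, Cst7, a cystatin gene, and Adam19, with mean intensities of 5.86, 6.0 and 10.7 in DP and 175, 137 and 166 in CD8SP. The pseudocount sets the size of these 3 changes, and no fold change is given. Rag1 fell by 3.70 ± 0.23 (adjusted p = 4.15e-05), while Rag2 (-3.64 ± 0.47) and F13a1 (-3.43 ± 0.15) also fell. Dusp15 was lower in CD8SP (adjusted p = 0.0112), with mean intensities of 272 in DP and -17.9 in CD8SP, so that no fold change is given. The remaining falls named by the rule, among genes that passed the filter on dim genes, were those of Tctex1d1 (-3.37 ± 0.24), Gpr162 (-3.30 ± 0.34), Ankrd6 (-3.04 ± 0.25) and Spo11 (-2.82 ± 0.18). Cd4 and Plxnd1 lay under the filter and are not ranked with them. Rag2, Tctex1d1, Gpr162 and Ankrd6, at 9.72 to 13.04 in CD8SP, and Klrd1 and Dapl1, at 13.8 and 16.4 in DP, lay near the pseudocount, so that the sizes of their changes depend on it. With the smallest pseudocount the changes were -4.47, -3.84, -3.83 and -3.46 for the 4 that fell and 4.63 and 3.85 for the 2 that rose. In total 2166 of 10916 genes changed, 1255 higher and 911 lower in CD8SP, and 419 and 208 of them at least 2-fold. The count was 3277 with the block, 1044 without DP replicate 1, 1018 without DP replicate 2 and 1087 without CD8SP replicate 2. Among the 16 leading genes, Dusp15 lost its call without DP replicate 1 or DP replicate 2 (adjusted p = 0.0699 and 0.0716), and Trpm1 did with the smallest pseudocount, where another probe gave 0.56 (0.0997).

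Over both steps 15 of 18 genes of the double-positive stage fell and 0 rose (15 adjusted over the list alone). Camera gave the list an adjusted p of 2.15e-12 (adjusted p = 0.501 with an estimated correlation). Limma's fry test called this list and no other (adjusted p = 0.0443). Ets2 fell by 2.10 ± 0.11, Aqp11 by 2.62 ± 0.36 and Ccr9 by 1.02 ± 0.09. Maturation and egress genes rose in 13 of 21 cases and fell in 2 (13 and 3 adjusted over the list alone). By camera, the list had an adjusted p of 0.000119 (adjusted p = 0.687 with an estimated correlation). Il7r, the interleukin 7 receptor, rose by 2.81 ± 0.30, Slfn1 by 3.32 ± 0.34, S1pr1 by 2.40 ± 0.32, Ccr7 by 1.97 ± 0.33 and Klf2, a transcription factor that drives S1pr1, by 1.82 ± 0.32. The 2 that fell were Ifngr1 (-1.60 ± 0.12) and S100a10 (-0.41, named after its value was seen). Of 15 genes of the CD8 list 7 rose and 2, again Cd8a (-0.98 ± 0.18) and Cd8b1 (-0.69 ± 0.13), fell (10 and 2 adjusted over the list alone), with Il2rb at 3.31 ± 0.23, Nkg7 at 3.0 ± 0.24 and Runx3 at 0.51 ± 0.18 (adjusted p = 0.0815, 0.0164 with the block, and from 0.00508 to 0.0387 under 4 other settings). The list had a camera adjusted p of 0.000248 (adjusted p = 0.662 with an estimated correlation). The 8 camera calls of this comparison held without each array, while Cd8a and Cd8b1 lost theirs without DP replicate 2 (adjusted p = 0.0599 and 0.0577).

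Proliferation genes were higher in CD8SP than in DP for 12 of 29 and lower for 0 (14 adjusted over the list alone, 20 with the block), with Cdc6 at 1.71 ± 0.32, Gins2 at 1.63 ± 0.30 and Mcm3 at 1.33 ± 0.17. Against other genes, camera gave an adjusted p of 5.94e-06 (adjusted p = 0.797 with an estimated correlation). Interferon-stimulated genes rose in 10 of 25 cases and fell in 0 (17 adjusted over the list alone, 19 with the block and 15 without CD4intCD8+ replicate 2), with Ifi27l2a at 2.73 ± 0.56, Ifit1 at 2.46 ± 0.48 and Bst2 at 2.22 ± 0.32. The camera adjusted p was 2.4e-05 (adjusted p = 0.797 with an estimated correlation). MHC class I genes rose in 10 of 18 cases, and Tap2 (-0.39, named after its value was seen) fell (12 and 1 adjusted over the list alone). Camera gave the list an adjusted p of 9.75e-05 (adjusted p = 0.662 with an estimated correlation). Nlrc5, a transactivator of class I genes, rose by 1.66 ± 0.33, H2-K1 by 1.19 ± 0.17 and H2-D1 by 1.08 ± 0.18. T cell receptor complex and signalling genes fell in 10 of 21 cases, and the ubiquitin ligase gene Cblb (0.84 ± 0.15) rose (11 and 1 adjusted over the list alone), with Cd28 at -1.47 ± 0.17 and Sla at -1.32 ± 0.10. By camera, the list had an adjusted p of 2.65e-05 (adjusted p = 0.671 with an estimated correlation). Of 29 transcription factors 12 fell and 6 rose (16 and 7 adjusted over the list alone), with Myb at -1.62 ± 0.12, Gfi1 at -1.42 ± 0.18, Gata3 at -1.14 ± 0.15 and Klf2 at 1.82 ± 0.32. The list had a camera adjusted p of 0.00327 (adjusted p = 0.662 with an estimated correlation). Cdc6 and Gins2 lost their calls without DP replicate 1 (adjusted p = 0.0617 and 0.0531), and Ifi27l2a, Ifit1 and Cblb without DP replicate 2 (from 0.0539 to 0.0678).

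The other 12 lists tested that are not markers of other cells were not called by camera between DP and CD8SP (adjusted p from 0.124 to 0.962, and adjusted p from 0.797 to 0.990 with an estimated correlation), and their called members went both ways except for cholesterol and CD4 lineage genes. Of 21 cytokine receptor genes 7 rose and 4 fell (8 and 5 adjusted over the list alone), with Tnfrsf1b at 2.10 ± 0.16 and Ifngr1 at -1.60 ± 0.12. Of 17 integrins and adhesion genes 6 rose and 3 fell (7 and 3 adjusted over the list alone), with Itgb7 at 1.51 ± 0.20 and Cd48 at 1.13 ± 0.15. Of 22 receptor response genes 4 rose and 8 fell (5 and 9), with Egr3 at 1.70 ± 0.20 and Itm2a at -1.29 ± 0.19, while Cd69 was not called (0.01 ± 0.24, adjusted p = 0.982). Of 16 genes of the NF-kappaB pathway 5 rose and 3 fell (5 and 3), with Bcl3 at 2.13 ± 0.24. Of 13 glycolysis genes 5 rose and 2 fell (5 and 2), with Ldhb, a lactate dehydrogenase subunit, at -2.41 ± 0.13 and Tpi1 at 1.35 ± 0.20. Of 15 cholesterol genes 5 rose and 0 fell (8 and 1, also with the block), with Idi1 at 1.33 ± 0.24; this list was called without the filter (adjusted p = 0.0427). Of 17 cell death regulators 2 rose and 3 fell (2 and 3), with Bcl2 at 1.12 ± 0.14, Fas at -1.54 ± 0.17 and Bcl2l1 at -1.81 ± 0.21, the last not called with the mean of all probes (adjusted p = 0.147). Of 9 chemokine and sphingosine phosphate receptors 3 rose and 1 fell (5 and 3), with S1pr4 at 1.41 ± 0.17; Cxcr4 had a log2 change of -0.66 ± 0.23 (adjusted p = 0.0730, 0.0355 with the block, and from 0.0108 to 0.0475 under 4 other settings). Of 8 Gimap genes 3 rose and 2 fell (3 and 3), with Gimap3 at 1.46 ± 0.18 and Gimap9 at -1.0 ± 0.14. Of 17 guidance genes 1 rose and 3 fell (1 and 3), with Ephb6 at -1.85 ± 0.18. Of 5 CD4 lineage genes 2, Tox (-1.19 ± 0.16) and Gata3, fell (2 rose and 2 fell adjusted over the list alone and with the block). Of 14 stress genes 1, Hspe1 (0.95 ± 0.13), rose and 1, Btg2 (-1.48 ± 0.22), fell (2 and 3, and 3 and 5 with the block).

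**Figure D2:**
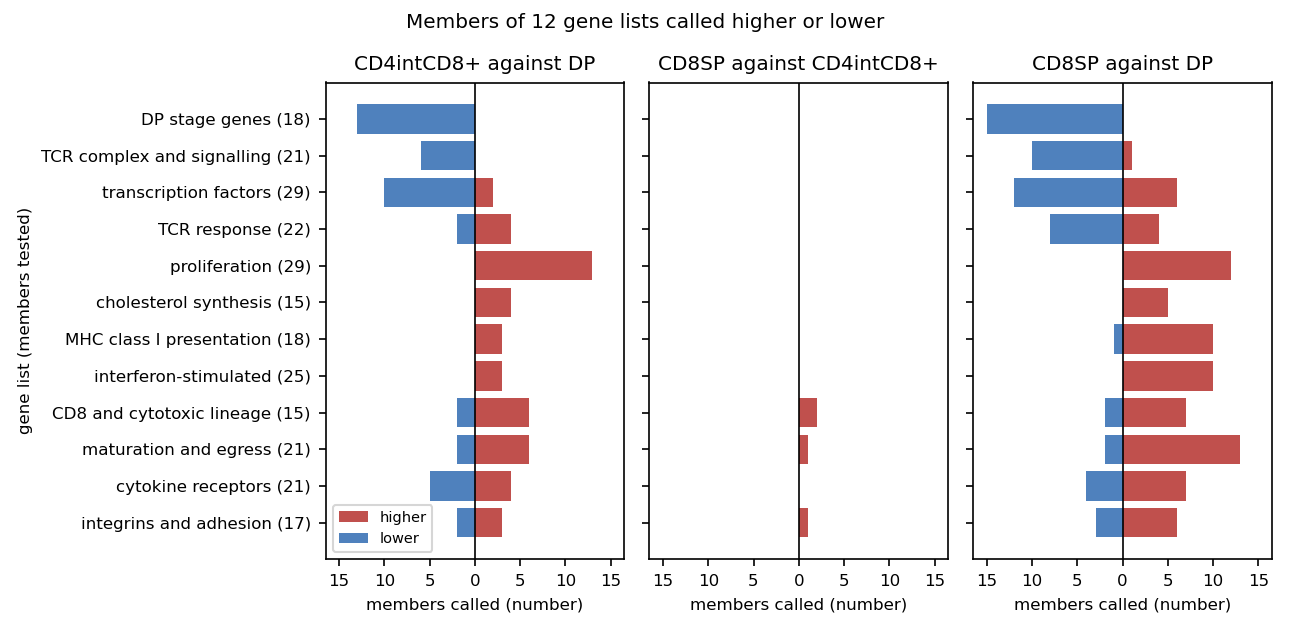
Number of tested members of 12 gene lists called higher or lower at an adjusted p under 0.05 in each of the 3 comparisons of stages. Genes of the double-positive stage are lower in 13 and 15 of 18 cases against DP, and few members of any list are called between CD4intCD8+ and CD8SP. Calls are from the fit with stage as the only term. With the replicate number as a block, 11 of 21 maturation and egress genes were higher in CD8SP than in CD4intCD8+, the most of the 12 lists.

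Over the 3 stages together 1657 of 10916 genes changed by the moderated F test (3104 with the block, 560 without DP replicate 1 and 460 without DP replicate 2). Genes called at the first step had the same sign of change at the second in 456 of the 749 that rose and 314 of the 528 that fell, 60.9% and 59.5%. The 2 steps share the CD4intCD8+ arrays. Simulations with no change at the second step gave 38.9% and 37.1% on average, and at most 43.1% and 40.5%, when genes varied independently. In a second set all genes followed the same random factors, taken from the differences between replicates, and arrays of a number deviated together. The average was then 42.7% and 41.2%. Of 196 such runs 29 and 19 gave as high a share, and 13 did so for both. That setting leaves genes no noise of their own, which can widen the spread between runs. The shares thus lie above independent noise, but with noise shared by all genes they do not exclude a second step without change. The contrast of CD4intCD8+ with the mean of the other stages, which tests whether the steps differ, called 1 gene, Nr4a3 (1.22 ± 0.12, adjusted p = 0.0449), while 1389 genes had an unadjusted p under 0.05. Its log2 means of 5.27 ± 0.05 (SD, n = 2) in DP, 7.66 ± 0.12 in CD4intCD8+ and 7.61 ± 0.01 in CD8SP show a rise at the first step and a level close to that in CD8SP. The Nr4a3 call was lost without either DP or either CD8SP array (adjusted p from 0.0983 to 0.399); without CD8SP replicate 2 another gene was called in its place. It was also lost with quantile normalization (0.0502), without the filter (0.0691), without the trend (0.119) and with the pseudocount at the 25th percentile (0.0515). With the mean of all probes the value was 0.71 (0.333), and 0 probes were called when each was tested on its own. The number called was 215 with the block, 6 with the actin covariate, 3 without CD4intCD8+ replicate 2 and 61 without CD4intCD8+ replicate 1, each time with Nr4a3 among them.

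Markers of other cell types moved in part with the stages. All 4 tested members of the dendritic cell list were higher in CD8SP than in DP: Cd74, the gene of the class II invariant chain (1.82 ± 0.18), and the MHC class II genes H2-Eb1 (1.96 ± 0.28), H2-Ab1 (1.73 ± 0.28) and H2-Aa (1.11 ± 0.25). In CD4intCD8+ 2 of them, Cd74 (1.43 ± 0.18) and H2-Ab1 (1.15 ± 0.28), were already higher than in DP (4 with the block and adjusted over the list alone). The list has 11 members, and the 4 tested are those that passed the filter on dim genes. Without the filter Itgax (-0.04), Flt3 (-0.34), Ciita (-0.53), Siglech (-0.09), Batf3 (0.02) and Xcr1 (0.46) were not called between DP and CD8SP. Of 5 tested macrophage and granulocyte markers 1, Ctss, which encodes cathepsin S, rose (1.84 ± 0.24 to CD4intCD8+, where 2 rose with the block, and 2.85 ± 0.24 to CD8SP), and of 5 tested B cell markers 1, Cd79b, was higher in CD8SP than in DP (0.90 ± 0.19, adjusted p = 0.0118). Of 3 tested natural killer markers Il2rb and Nkg7, which are also in the CD8 list, rose. Among 3 tested markers of double-negative thymocytes Hhex (1.12 ± 0.24) rose and Notch3 (-1.0 ± 0.16) fell between DP and CD8SP. Adjusted over the list alone, these counts between DP and CD8SP were the same. None of the 2 epithelial, 2 erythroid or 3 gamma delta T cell markers tested by limma was called in any comparison with the settings reported. The gamma delta marker Trgv4 rose by 0.86 between DP and CD8SP. Receptor genes other than the transgene are not assembled in these mice, so this rise does not show gamma delta T cells. Limma called Trgv4 with the 60th-percentile filter (adjusted p = 0.0450) and the mean of all probes (0.0494). It was also called with only the 4 arrays compared (0.0243) and with the pseudocount at the 25th percentile (0.0498). Without CD8SP replicate 1 the erythroid marker Alas2 changed by -1.20, against -0.71. With the block 1 gamma delta marker rose from DP to both later stages and 1 erythroid marker fell between DP and CD8SP, where 2 gamma delta markers rose adjusted over the list alone. The 6 marker lists with fewer than 5 tested members had no camera test, and the B cell and myeloid lists were not called by camera between DP and CD8SP (adjusted p = 0.40 and 0.273; adjusted p = 0.799 and 0.687 with an estimated correlation). Calls were lost without DP replicate 1 or DP replicate 2 for H2-Aa (adjusted p = 0.0514 and 0.0999), Cd79b (0.0782 and 0.0552) and, at the first step, H2-Ab1 (0.171 and 0.114). They were also lost without CD8SP replicate 2 for H2-Aa (0.0924), without either CD8SP array for Cd79b (0.0565 and 0.0569), without CD4intCD8+ replicate 2 for H2-Ab1 (0.134) and without DP replicate 2 or CD8SP replicate 1 for Hhex (0.087 and 0.0675). With the mean of all probes H2-Ab1 changed by 1.02 to CD8SP (adjusted p = 0.111) and by 0.59 to CD4intCD8+ (0.376), and was not called. At the first step it was also lost without the trend (0.0601) and with the actin covariate, at 0.50 (0.448).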

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

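The contrast behind the first result was fixed before the data were examined; the count of probes without a gene name and the comparison of hybridization controls were chosen after the data were seen. With the settings reported, Nr4a3 was the only gene called for a first step that differed from its second: CD4intCD8+ lay 1.22 ± 0.12 (log2, SE) above the mean of DP and CD8SP (limma adjusted p = 0.0449), both CD4intCD8+ arrays lying above both DP arrays. The call was lost without either DP or either CD8SP array (adjusted p from 0.0983 to 0.399), and without CD8SP replicate 2 another gene was called in its place. It was also lost with quantile normalization (0.0502), without the filter (0.0691), without the trend (0.119), with the pseudocount at the 25th percentile (0.0515) and with the mean of all probes, where the value was 0.71 (0.333); when each probe was tested on its own 0 were called. Other settings called more genes than this 1: 215 with the replicate block, 61 without CD4intCD8+ replicate 1, 6 with the actin covariate and 3 without CD4intCD8+ replicate 2.

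Among 2580 probes that passed the same filter but carry no single gene name, and so enter no comparison of the report, 301 differed between DP and CD8SP, 162 higher and 139 lower in CD8SP; 159 differed between DP and CD4intCD8+ and 3 between CD4intCD8+ and CD8SP.

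The BioB hybridization control, RNA added in a fixed amount before hybridization, was 0.39 higher on the log2 scale in CD4intCD8+ than in DP and 0.34 higher in CD8SP than in DP. Its intensities were 264 and 258 on the DP arrays, 306 and 382 on the CD4intCD8+ arrays and 334 and 327 on the CD8SP arrays. The corresponding differences were 0.26 and 0.26 for BioC, 0.24 and 0.21 for BioDn and -0.02 and -0.11 for CreX.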

How the results depend on the processing

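The actin covariate was chosen after the data were seen; the other alternatives were fixed before. Leaving out 1 array, the count of changed genes ran from 187 to 1399 for CD4intCD8+ against DP, from 6 to 70 for CD8SP against CD4intCD8+, from 1018 to 2345 for CD8SP against DP, from 0 to 61 for CD4intCD8+ against the mean of the others, and from 460 to 2205 for the F test. These fits have fewer samples, and the lone array of a stage is assumed to vary like the other groups; the number of called lists stayed between 24 and 27. The replicate block gave 2562, 227, 3277, 215 and 3104 genes in the same order, against 1277, 13, 2166, 1 and 1657. Every gene of the 3 pairwise counts kept its call under the block, 67 of 352 named gene contrasts became called and 0 lost their call, and of the lists maturation and egress (first step, adjusted p = 0.0263) and chemokine receptors (second step, 0.0200) became called; the block changed no other list call.

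The mean of all probes gave 764, 2 and 0 genes for the steps and the contrast with the mean of the others, and no intensity trend gave 801 for the first step and 0 for that contrast. That contrast also gave 0 genes with quantile normalization, without the filter, with the pseudocount at the 25th percentile and for each probe on its own, where limma gave 1389 genes at an unadjusted p under 0.05 with the settings reported. Without CD8SP replicate 2 it gave 1 gene, but not the gene reported, Nr4a3 (adjusted p = 0.111). For the second step, the 60th-percentile filter gave 8 genes and only the 4 arrays compared 8 (fewer genes or fewer samples by construction). The actin covariate gave 406 genes for the first step, 34 for the second and 6 for the contrast with the mean of the others; 1 more term was fitted to 6 arrays. A 2-fold threshold left 301 and 627 genes for CD4intCD8+ and CD8SP against DP, by construction. Camera with an estimated correlation called 0 lists and fry 1, against 26. Except where construction is named, the cause was not tested.

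The median of the proliferation list at the second step, -0.20, became 0.15 with the actin covariate and ran from -0.45 to 0.13 when 1 array was left out. The median of the receptor response list at the first step, -0.09, became 0.34 with the actin covariate and 0.16 without CD4intCD8+ replicate 2. The log2 change of Jund at the first step, -0.55 ± 0.13, became 0.023 with the mean of all probes. For these 3 the cause was not tested. Of 2112 values of named genes with 1 array left out, 1852 kept their direction and side of the threshold, 196 lost a call, 64 gained 1 and 0 reversed; of 4085 under the other settings the counts were 3866, 102, 116 and 1. For lists they were 368, 14, 12 and 2 of 396, and 761, 10, 10 and 2 of 783. Signs of uncalled values that turned, 67 of them, are counted as kept. Of the 352 named gene contrasts, those without a value were 113 with the 60th-percentile filter, 21 with the mean of all probes and 5 with the smallest pseudocount. At the second step 11 higher and 2 lower genes were reported; quantile normalization gave 11 and 4, and leaving out CD8SP replicate 2 gave 5 and 9, which turns the balance over, with 5 of those 14 genes among the 13. Why that array sets the balance was not tested. With the smallest pseudocount Trpm1 changed by 0.18 at the first step against 2.89, and Clcf1 by 0.31 at the second against 1.63. Another probe stood for each of the 2 genes there, as for no other gene of the 10916, while the probes reported gave 3.70 and 1.73. Signal over background limits dim genes: 3.60% of values lay below 0, and changes of genes near the pseudocount of 5.84 depend on it.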

Other observations

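The gene families of this part and the mixture test on medians were chosen after the results were seen; the tests of RNA integrity, of dendritic and B cells, and of mixture gene by gene were written before their results, as was the reading of RNA integrity with separate DP arrays, which was added last. Ribosome biogenesis factors were higher after the DP stage: 17 of 43 rose from DP to CD4intCD8+ and 24 of 43 from DP to CD8SP, and 0 fell (limma camera adjusted p = 3.4e-07 and 3.42e-09 over 30 family tests; adjusted p = 0.520 with an estimated correlation for both). At the first step Rrp12 rose by 2.01, Nhp2 by 1.55, Utp20 by 1.37 and Gar1 by 1.30 on the log2 scale. Of 76 mitochondrial ribosomal protein genes 14 rose at the first step and 14 from DP to CD8SP, where 1 fell (camera adjusted p = 2.98e-08 and 4.06e-06; adjusted p = 0.520 with an estimated correlation for both). Aminoacyl-tRNA synthetase genes rose in 3 of 19 cases at the first step and in 10 of 19 from DP to CD8SP, among them Vars and Gars (camera adjusted p = 0.00215 and 8.91e-05; adjusted p = 0.520 with an estimated correlation for both). Of 14 chaperonin genes 4 and 5 rose (camera adjusted p = 0.00064 and 0.00082; adjusted p = 0.520 with an estimated correlation for both). The other families were mixed: initiation factors were not called (camera adjusted p = 0.363 and 0.428), nor were amino acid transporters, of which 3 rose and 3 fell at the first step (0.976 and 0.448). Cytosolic ribosomal protein genes were called at the first step (0.0144) but not between DP and CD8SP (0.428), as were those of the proteasome (0.00741 and 0.122), while respiratory chain genes were called in both (0.00019 and 0.0393). At the second step ribosome biogenesis and tRNA synthetase genes were called up (4.74e-05 and 0.00672) and cytosolic ribosomal and respiratory chain genes down (0.0362 and 0.0431), with 0 single members called. With an estimated correlation the adjusted p of all families lay from 0.520 to 0.976 in every comparison, and differences between families were not tested. Of 233 zinc finger genes 7 rose and 23 fell between DP and CD8SP (camera adjusted p = 0.0252; adjusted p = 0.520 with an estimated correlation), with Zfp770 at -1.43 and Zfp52 at 1.84.

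The actin 3' to 5' ratio also differed between the 2 stages compared for the 1277 genes, at 2.37 and 3.47 in CD4intCD8+ against 1.98 and 2.14 in DP. The Gapdh 3' to 5' ratio was 1.42 and 1.99 against 1.37 and 1.53, so that CD4intCD8+ replicate 1 lay between the DP arrays. If RNA integrity were the whole cause, the change in CD4intCD8+ replicate 1 would be 0.27 of that in replicate 2, as the actin ratios are. Among the 1399 genes called from replicate 2 alone, the median ratio was 0.657 (middle 50% of genes from 0.467 to 0.860), and 97.0% had the same sign in replicate 1, which argues against integrity as the whole cause. Both changes are measured from the same DP arrays, which draws the ratio and the signs together. Simulations in which integrity was the whole cause were made at the full effect and at 0.5 of it. They gave a median ratio of at most 0.294 and 0.340, and the same sign in at most 88.5% and 94.7% of genes. Noise in these runs was drawn independently for each gene and array. Noise shared between genes was not simulated and may widen these limits, so the argument holds only as far as noise is independent. With a separate DP array for each CD4intCD8+ array, the median ratio was 0.710 in one way and 0.617 in the other (lower quartiles 0.466 and 0.377). The actin ratios of the same arrays were 0.368 and 0.178, and the highest simulated medians, reached at 0.5 of the effect, 0.357 and 0.377. How far single genes follow integrity stays open. The count was 473 without CD4intCD8+ replicate 2 and 406 with the actin covariate, but it was also 317 and 187 without DP replicates 1 and 2, whose ratios are low, so the counts do not decide. The change of stage that the design names stays open and cannot be separated further with 2 arrays per stage.

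The transcripts of MHC class II genes and Cd74, together called the class II genes here, were higher in CD8SP than in DP. They may come from other cells in the sort or from the thymocytes themselves. For dendritic cells, 16 other dendritic cell transcripts had a median rise of -0.19 in intensity, -0.0023 of the median rise of 81.5 of the 4 class II genes. Several of the 16 lie near the floor, Cst3 has a high baseline of 538, and Naaa rose from 42.3 to 138. Ctss, a called gene of the myeloid list that such cells also carry, rose from 129 to 944 and goes with dendritic cells. Counted in, the median of 17 transcripts was 0.0061 of the class II rise (bootstrap interval -0.0468 to 0.0787), under the bound of 0.1. Transcripts near the floor can stay flat with or without dendritic cells, so that this median does not decide and dendritic cells stay open. For B cells the median rise of 7 transcripts was 0.151 of the class II rise, between the bounds set beforehand, with Cd79b called. These transcripts alone thus cannot tell B cells apart from expression by the thymocytes. The mice lack Rag2 and assemble no receptor genes other than the transgene, which argues against mature B cells as the source. Whether precursors without a receptor were among the sorted cells was not tested. A sort on CD4 and CD8 would remove most B cells, and no biological explanation was tested.

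CD4intCD8+ levels lay between those of DP and CD8SP for many genes, and a candidate explanation is a sort that mixed DP with CD8SP cells. The share of DP read from 208 genes that are lower in CD8SP was 0.22 in the median and that from 419 genes that are higher 0.41, a difference of 0.184 (0.188 and 0.175 in the replicate pairs, and from 0.092 to 0.272 over 8 combinations of arrays), which does not pass the bound of 0.2 set against a mixture. The difference also lies outside the 0.1 within which a mixture would keep it, except in the lowest of the combinations, so that it lies between the bounds. A second test, added because that one did not decide, asked whether genes have shares of their own: the shares in replicate pair 1 and pair 2 had a Spearman correlation of 0.647 across genes, 0.642 (bootstrap interval 0.576 to 0.698) for genes higher and 0.506 (0.378 to 0.614) for genes lower in CD8SP, against at most 0.226 after shuffling. A single mixture of cells gives every gene the same share, while Rag1 showed 0.041, Klrd1 0.927 and Samhd1 0.954, but the interval for the lower genes spans the bound of 0.5 set beforehand and probes that respond in a non-linear way also give genes different shares. The bound itself was passed by both correlations; that the interval must clear it too was asked only after 0.506 was seen. The prediction for a mixture with the same share for every gene was a correlation under 0.2, and both intervals lie above that value. This argues against such a mixture for the 208 and 419 genes read, as far as probes respond in proportion to RNA. Probe response was not tested, so a mixture read through non-linear probes cannot be told apart from a stage with a programme of its own.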
